A study of Homo sapiens with 9 samples.

How the data were processed

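Total RNA of 9 libraries was measured by ribosomal RNA depletion (Ribo-Zero) and stranded, single-end sequencing of 75 bp reads on a NextSeq500, per the labels' protocols. The values are counts of reads per gene, as deposited by the authors in a separate table for each library, and were not normalized. Per the submitters' processing notes, Bowtie2 2.5.0, featureCounts 2.0.1 and DESeq2 2.11.40.6 were used with the hg38 build; the order, the settings and the gene annotation were not given in the sources used here. Bowtie2 does not align reads across introns, so reads over exon junctions can be lost or placed on processed pseudogenes. Genes with many short exons or many pseudogene copies can thus be undercounted. The strand setting of the counting was not given in the sources used here, so that antisense and overlapping genes (FOXD3-AS1, FOXD3) are uncertain. Closely related genes that can share reads (the MYH family, ACTA1 and ACTC1, HSPA1A and HSPA1B, troponins) are uncertain too. Some genes chosen by the naming rule or after their values were seen are not reported here.

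Each table held 28395 gene identifiers with no duplicates, of which 27745 matched a symbol in a RefSeq gene table of GRCh38.p14 and 650 did not. Coordinates come from that table. Of the genes of 27 lists written before the data were examined, 485 were matched and 1 was not (MYMX). The lists covered muscle structure and differentiation (sarcomere, myogenic progenitor and myoblast, myogenic differentiation and fusion, excitation-contraction coupling and calcium, neuromuscular junction, dystrophin complex and membrane repair, slow fibre, fast fibre), metabolism and growth (oxidative metabolism, glycolysis and glycogen, cell cycle, cholesterol and fatty acid synthesis), matrix and adhesion (integrin adhesion, basement membrane, interstitial matrix), signalling (YAP and TEAD targets, FGF, ERK and cAMP response, Notch pathway, stress and unfolded protein response, interferon response) and other cell types (pluripotency, neural and Schwann cell, fibroblast and mesenchyme, smooth muscle, cardiac muscle, endothelial, epithelial).

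Samples were grouped by their labels into MyoB, MyoT-Lam and MyoT-Gtx, with 3 libraries each, and the 3 pairs of groups were compared. Library totals ran from 15062749 to 52716558 counts. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 17409 genes with 99.94% of reads and left out 10986. Libraries were scaled by TMM factors of 0.91 to 1.16. Each contrast was tested with edgeR's quasi-likelihood test on all 9 libraries, which shared 1 estimate of the spread (biological coefficient of variation 5.5%), with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM are counts per library total scaled by the TMM factors, given as mean ± SD. Gene lists with at least 3 tested members, 26 of the 27, were tested with limma's camera on log CPM with a prior count of 2 and a preset correlation between genes of 0.01, again with Benjamini-Hochberg adjustment over the lists. Camera was repeated with the correlation estimated for each list, and fry tested whether the genes of a list moved on balance in a direction. Counts adjusted over the list alone apply the adjustment to the members of that list only. Folds against a group with 0 reads are lower bounds against a floor of 3 counts over the group, and against 1 to 3 reads they are ratios with 95% counting intervals.

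The genes named were set before the data were examined as the 6 largest increases and the 6 largest decreases per contrast with an adjusted p under 0.05 and at least 5 CPM in the higher group, up to 2 members per list with the smallest adjusted p, and PAX7, MYF5, MYOD1, MYOG, MYMK, MYH3, DMD and MKI67 in every contrast. Genes named beyond it are said to be chosen after their values were seen.

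The count test was checked on simulated counts with the libraries' own depths and the mean expression of MyoB in every library. The 200 changed genes were taken from those with enough expected reads in the shallowest library. Recovery at myotube means or in genes with few reads was not simulated. The test recovered 82.1% of genes changed 1.5-fold among 16371 genes for MyoT-Lam against MyoB. It recovered 76.1% among 16377 genes for MyoT-Gtx against MyoB and 82.1% among 16355 genes between the substrates. False calls made up 4.61%, 2.96% and 8.11%. For the sharing of the MyoB libraries, unchanged groups were simulated 20 times, with all libraries, MyoB included, drawn around the MyoB means. Alternatives set before the data were examined were RLE and upper-quartile factors, library totals alone, DESeq2's Wald test, no filter beyond 1 read in any library, a filter of 5 CPM in at least 3 libraries, fits of only the 6 libraries compared, the replicate number as a block, a test against a 1.5-fold change, each library left out in turn, and fry and the estimated correlation for lists. Offsets for each library's trend with GC content and transcript length, fitted with a loess span of 0.5, were added for the comparison of substrates after the data were examined. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.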

Results

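A human induced pluripotent stem cell line, that is, cultured cells reprogrammed to a state from which muscle and other tissues can be derived, was the source of the myoblasts and myotubes profiled here. The series set out to profile both cell states and, for the myotubes, culture on different substrates. Total RNA was depleted of ribosomal RNA and sequenced as stranded, single-end 75 bp reads. The 9 libraries formed 3 groups of 3 replicates. MyoB libraries came from myoblasts, the proliferating precursors of muscle fibres, plated on Geltrex, a basement membrane extract, at 25K cells per cm2. Their amplification medium held 10% serum, 4 µM forskolin, 10 ng/ml heregulin, 10 ng/ml FGF2 and 100 ng/ml IGF1. Myotubes, the multinucleated cells made by fusion of myoblasts, were plated at 100K cells per cm2 and kept for 7 days in a maturation medium, either on Laminin-521, a laminin isoform (MyoT-Lam), or on Geltrex (MyoT-Gtx).

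The MyoB libraries held 21191759, 24711032 and 23401086 counts in genes, the MyoT-Lam libraries 31166843, 23045448 and 52716558, and the MyoT-Gtx libraries 23919750, 25258460 and 15062749. With these depths, 3 reads in a library, taken as its detection floor, corresponded to between 0.0623 and 0.208 CPM, the counts scaled to a common library size. Within groups, the correlation of log expression across genes between libraries was 0.9914 to 0.9965, between MyoB and myotube libraries it was 0.8789 to 0.886, and between MyoT-Lam and MyoT-Gtx libraries it was 0.9915 to 0.9956. All replicate pairs of a group differed by more than sampling noise, with a chi-square of 4.78 to 18.3 per gene. The first principal component held 92.1% of the variance and separated MyoB from both myotube groups. MyoT-Gtx replicate 3, the shallowest library, stood apart on the second component, which held 1.9% of the variance, with a score of 31.49 against -10.92 to 3.44 in the other libraries. Among the myotube libraries alone it stood apart on the first component, which held 31.9% of the variance, with 31.94 against -10.54 to -3.23. The composition of the libraries also differed between cell states. TTN, which encodes the giant sarcomere protein titin, took 0.403% ± 0.02 of counts in MyoB, 3.99% ± 0.492 in MyoT-Lam and 3.53% ± 0.334 in MyoT-Gtx (mean ± SD, n = 3, as for all group values given in this form). The 10 most abundant genes took 7.90% to 8.82% of counts in MyoB libraries, against 14.4% to 15.5% in myotube libraries. Small nucleolar, small nuclear, ribosomal and other short or structural RNA genes, counted together, took 4.42% to 5.19% in MyoB and 6.06% to 8.42% in the myotubes. The labels say that triplicates were prepared but not that they were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

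The comparison of MyoT-Lam with MyoB asks how myotubes on Laminin-521 differ from the myoblasts. Of 41 sarcomere genes 38 rose (a list call that was lost with an estimated correlation, adjusted p = 0.107), and all 27 cell cycle genes fell. MYBPC1, which encodes a myosin-binding protein of the sarcomere, the contractile unit of muscle, rose from 14.5 ± 0.722 CPM in MyoB to 1023 ± 19.0 CPM in MyoT-Lam, a 70.8-fold increase. MYH3, the embryonic myosin heavy chain, rose from 956 ± 85.1 to 6891 ± 399 CPM, and MYOG, a transcription factor of myogenic differentiation, from 200.5 ± 6.55 to 707 ± 46.1 CPM. MKI67, a marker of proliferating cells, dropped from 751 ± 40.5 to 65.2 ± 4.83 CPM, 11.5-fold lower. POSTN, which encodes the matrix protein periostin, fell 16.4-fold, from 554 ± 25.2 to 33.6 ± 2.04 CPM.

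The 8 genes fixed for all comparisons covered the steps of the myogenic programme. PAX7, a transcription factor of muscle stem cells, had a log2 difference of -0.28 (SE 0.048, adjusted p = 7.05e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, as for all adjusted p-values of single genes). MYF5, an early myogenic determination factor, fell by 1.83 on the log2 scale, from 115 ± 3.64 to 32.4 ± 0.583 CPM. MYOD1, which also acts in determination, rose by 0.49 (adjusted p = 1.65e-05) and MYOG by 1.82 (SE 0.056, adjusted p = 7.6e-14). MYMK, whose product myomaker drives fusion, rose by 2.45, MYH3 by 2.85 and DMD, which encodes dystrophin, by 2.78. MKI67 fell by 3.52 (SE 0.068, adjusted p = 3.39e-16). On GRCh38, PAX7 (gene 5081) lies on chromosome 1 from 18630846 to 18748866, MYOG (gene 4656) on chromosome 1 from 203083129 to 203086012, and MYMK (gene 389827) on chromosome 9 from 133514586 to 133524959. MYH3 (gene 4621) spans 10628532 to 10678417 of chromosome 17, DMD (gene 1756) spans 31119222 to 33339388 of chromosome X, and MYBPC1 (gene 4604) spans 101594971 to 101695841 of chromosome 12. MKI67 (gene 4288) lies on chromosome 10 from 128096659 to 128126423.

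**Figure D1:**
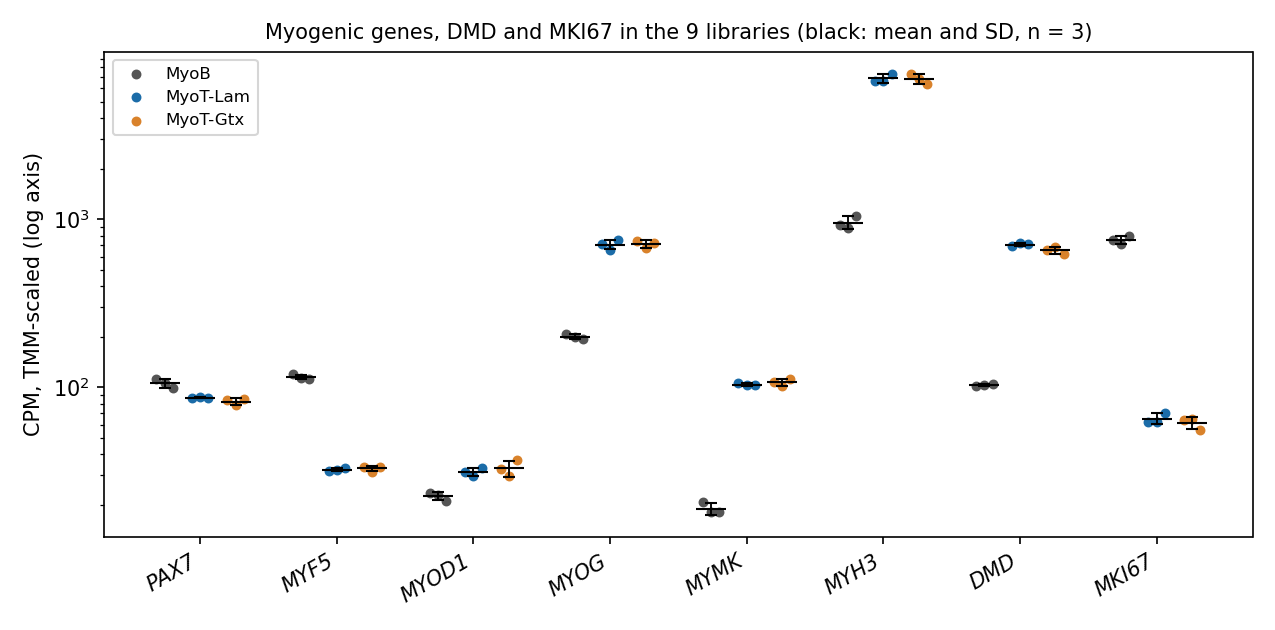
Expression of 8 myogenic and marker genes in CPM (log axis) in the 9 libraries, with points for single libraries and black marks for the group mean and SD (n = 3). MYOG rises from 200.5 CPM in MyoB to 707 in MyoT-Lam and 715 in MyoT-Gtx, while MKI67 drops from 751 to 65.2 and 61.4 CPM.

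Among genes with at least 5 CPM in the higher group, the steepest increases were in genes with few or no reads in MyoB. FATE1, known for expression in testis, and HS6ST3, a heparan sulfate sulfotransferase, had 0 reads in MyoB and were at least 226-fold and at least 190-fold higher in MyoT-Lam, against a floor of 3 counts over the group. SLN encodes sarcolipin, an inhibitor of the calcium pump of the sarcoplasmic reticulum; it had 3 reads in MyoB and 49.5 ± 1.23 CPM in MyoT-Lam, a ratio of 1310 with a 95% counting interval of 447 to 6350. ADCY2, an adenylyl cyclase, had 1 read in MyoB and a ratio of 987 (177 to 39000), and the long noncoding RNA FOXD3-AS1 had 2 reads and a ratio of 501 (138 to 4140). PRKAA2, a catalytic subunit of AMP-activated protein kinase, rose by 8.82 on the log2 scale, from 0.140 ± 0.0263 to 65.1 ± 0.848 CPM. Among the steepest decreases, MYOCD, a coactivator of smooth and cardiac muscle genes, had 2 reads in MyoT-Lam and was 255-fold lower than in MyoB (70.1 to 2110). L1CAM, a neural adhesion molecule, dropped from 149.7 ± 7.005 to 2.38 ± 0.208 CPM, while the carboxypeptidase gene CPA4 fell by 5.98 and the thrombin receptor family gene F2RL2 by 5.89. ID3, an inhibitor of myogenic and other helix-loop-helix factors, fell by 5.42, from 77.0 ± 4.04 to 1.83 ± 0.235 CPM, and NT5E, a cell surface enzyme that forms adenosine, fell by 5.41. SLN (gene 6588) lies on chromosome 11 from 107707378 to 107712056, PRKAA2 (gene 5563) on chromosome 1 from 56645314 to 56715335, and L1CAM (gene 3897) on chromosome X from 153861514 to 153886173. Intervals and floors cover counting error only.

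Muscle gene lists moved largely one way. Of 41 sarcomere genes tested, 38 rose, 2 fell and 1 was not called (median log2 difference 3.35, camera adjusted p = 3.46e-14; adjusted p = 0.107 with an estimated correlation). MYBPC2 rose by 5.18. The exceptions were MYH7, the slow cardiac-type myosin heavy chain, which fell by 1.21, TMOD4, a tropomodulin, which fell by 1.11, and TNNT1, the slow skeletal troponin T, at -0.07 (adjusted p = 0.565). TNNT1 was called lower under scaling by library totals (-0.35, adjusted p = 0.00249). TMOD4 had few reads, with 1.14 to 1.47 CPM in MyoB and 0.498 to 0.863 CPM in MyoT-Lam. In the myogenic differentiation and fusion list 21 of 22 genes rose (median 2.85, camera adjusted p = 1.37e-10; adjusted p = 0.066 with an estimated correlation), among them FBXO32, a muscle ubiquitin ligase subunit, by 4.62 and the myosin chaperone UNC45B by 3.54. CDKN1C, a cell cycle inhibitor, fell by 0.38. All 22 excitation-contraction coupling and calcium genes rose (median 2.77, camera adjusted p = 1.37e-10), including CACNA1S, the muscle voltage sensor, by 4.00 and ATP2A1, the fast muscle calcium pump, by 4.13. For the neuromuscular junction, 13 of 16 genes rose, 1 fell and 2 were not called (median 1.12, camera adjusted p = 0.000379; adjusted p = 0.0811 with an estimated correlation). The agrin receptor gene LRP4 rose by 3.01 and the acetylcholine receptor subunit CHRND by 2.38, while ETV5, a transcription factor, fell by 0.78. CHRNA1 and CHRNE, further receptor subunits, differed by -0.01 and 0.33 (adjusted p = 0.901 and 0.374). CHRNA1 was called lower under scaling by library totals (-0.29, adjusted p = 9.18e-06). In the list for the dystrophin complex and membrane repair 13 of 19 genes rose and 6 fell (median 1.47, camera adjusted p = 0.0101; adjusted p = 0.0811 with an estimated correlation), with the syntrophin SNTB1 higher by 2.74. Of 13 fast fibre genes 12 rose (median 4.01, camera adjusted p = 4.92e-06; adjusted p = 0.131 with an estimated correlation), and the exception PVALB, a calcium buffer, fell by 3.82. Of 11 slow fibre genes 8 rose, 2 fell and 1 was not called (median 1.67, camera adjusted p = 0.0393; adjusted p = 0.356 with an estimated correlation and 0.104 with a stricter filter on low counts). CASQ2, a calcium store protein, rose by 4.49 and MYOZ2, a Z-disc protein, by 3.86, whereas MYH7 and the slow tropomyosin TPM3 (-1.36) fell. The myogenic progenitor and myoblast list split, with 6 of 19 genes higher and 13 lower (median -0.42, camera adjusted p = 0.128). DLK1, an imprinted gene for a Notch-related membrane protein, rose by 5.82 within it, from 7.00 ± 0.389 to 395 ± 15.1 CPM.

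Metabolic and cell cycle genes followed. All 27 cell cycle genes fell (median -2.92, camera adjusted p = 5.46e-13), among them TOP2A, a DNA topoisomerase, by 3.16 and CCNB1, a mitotic cyclin, by 3.28. Of 18 cholesterol and fatty acid synthesis genes 16 fell (median -1.07, camera adjusted p = 2.87e-05). SCD, the stearoyl-CoA desaturase, dropped from 1267 ± 22.2 to 323 ± 1.96 CPM. The sterol regulator SREBF2 was 0.19 higher, a direction that turned to -0.09 when libraries were scaled by their totals alone. Of 17 oxidative metabolism genes 12 rose, 3 fell and 2 were not called (median 0.53, camera adjusted p = 0.0074; adjusted p = 0.107 with an estimated correlation). PPARGC1A, a coactivator of mitochondrial genes, rose by 3.75 and SLC25A4, the mitochondrial ADP/ATP carrier, by 1.61. The exceptions were the mitochondrial creatine kinase CKMT2 (-0.38), the respiratory chain gene UQCRC1 (-0.54) and the carnitine palmitoyltransferase CPT1B (-0.63), whose call ended without MyoB replicate 2 (-0.56, adjusted p = 0.0605) and without MyoT-Lam replicate 3 (-0.51, adjusted p = 0.0851). DESeq2 did not call CPT1B (-0.59, adjusted p = 0.104). COX7A1, a muscle subunit of cytochrome c oxidase, and LDHB, a lactate dehydrogenase subunit, differed by 0.21 and 0.04 and were not called. LDHB was called lower under scaling by library totals (-0.24, adjusted p = 7.78e-05). For glycolysis and glycogen, 13 of 16 genes rose, 2 fell and 1 was not called (median 0.83, camera adjusted p = 0.000989; adjusted p = 0.248 with an estimated correlation). The muscle enolase ENO3 rose by 2.91, and the exceptions LDHA, lactate dehydrogenase, and PKM, pyruvate kinase, fell by 1.56 and 0.52. GAPDH was at 0.02 (adjusted p = 0.721), or called lower under scaling by library totals (-0.26, adjusted p = 2.54e-05).

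**Figure D2:**
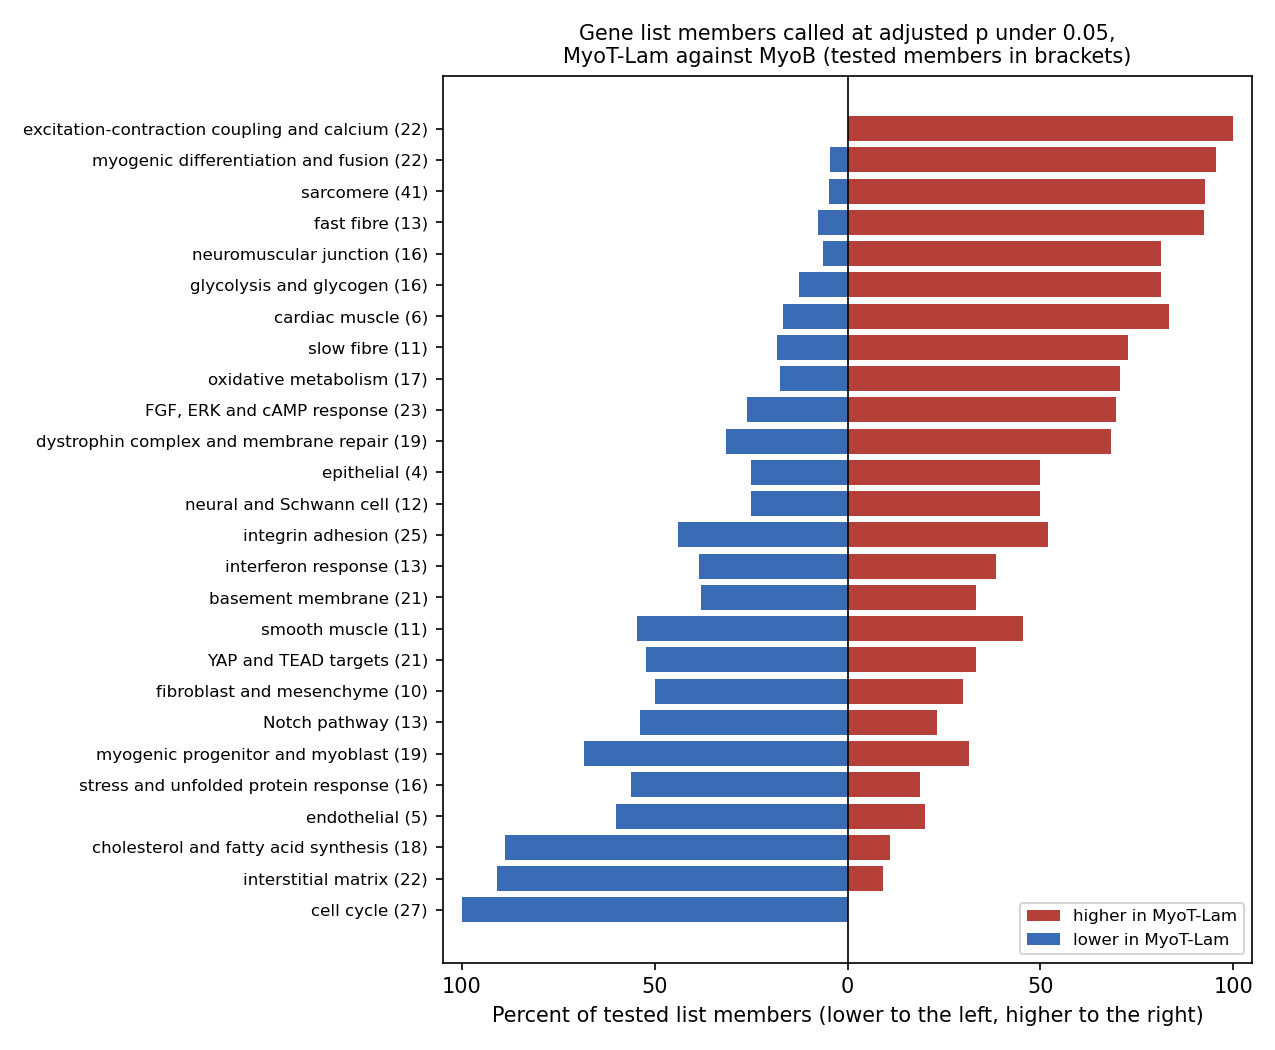
Percent of the tested members of each gene list called higher (right) or lower (left) in MyoT-Lam than in MyoB at an adjusted p under 0.05, with the number of tested members in brackets. All 22 excitation-contraction coupling genes are higher and all 27 cell cycle genes are lower.

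Of 22 interstitial matrix genes 20 fell and 2 rose (median -1.31, camera adjusted p = 4.05e-07). LOX, a collagen crosslinking enzyme, fell by 2.82 and FN1, which encodes fibronectin, by 2.64. ELN, the elastin gene, rose by 4.15, and SPARC, a collagen-binding protein, by 0.14, a direction that turned to -0.14 under scaling by library totals (adjusted p = 0.00657) and a call that ended without MyoB replicate 3 (0.12, adjusted p = 0.0557) and without MyoT-Lam replicate 1 (0.13, adjusted p = 0.0535). Basement membrane genes went both ways, 7 higher, 8 lower and 6 not called of 21, with a median of 0.10, a mean of 0.07 and a camera direction that was down (adjusted p = 0.843). LAMA2, the laminin chain of muscle, rose by 3.55, from 43.7 ± 1.61 to 511 ± 14.9 CPM, while the collagen gene COL4A1 fell by 3.05. In the integrin adhesion list 13 of 25 genes rose and 11 fell (camera adjusted p = 0.578), with the laminin-binding ITGA6 higher by 1.72 and the collagen-binding ITGA1 lower by a log2 difference of -2.23. YAP and TEAD target genes split into 7 higher, 11 lower and 3 not called of 21 (camera adjusted p = 0.284), and CCDC80, a secreted protein gene, fell by 3.31. The FGF, ERK and cAMP response list had 16 of 23 genes higher and 6 lower (median 0.66, camera adjusted p = 0.0224; adjusted p = 0.309 with an estimated correlation). EGR1, an immediate early gene, rose by 2.01 and the FGF target ETV4 fell by 2.72; the myoblast medium alone was described as holding FGF2 and forskolin. Notch pathway genes split into 3 higher, 7 lower and 3 not called of 13 (camera adjusted p = 0.317), with the receptor NOTCH3 at -2.29 and the target HES1 at 1.89. In the stress and unfolded protein response list 3 of 16 genes rose and 9 fell (camera adjusted p = 0.207), among them ATF3 (-1.99) and the chaperone gene DNAJB1 (-0.89). Interferon response genes went both ways, 5 higher and 5 lower of 13, with a median of 0.07, a mean of -0.34 and a camera direction that was down (adjusted p = 0.793). IFIT1 fell by 3.13 and IFI44L by 3.50, both of them induced by interferon.

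Markers of other cell types gave no list call by camera with the filter used here. The neural and Schwann cell list had 6 of 12 genes higher and 3 lower (camera adjusted p = 0.272). It was called higher under a stricter filter on low counts, which left 5 of its genes (median 3.09, adjusted p = 0.00394). DCX, a microtubule protein of young neurons, rose from 298 ± 6.23 to 2444 ± 18.5 CPM and the neurofilament gene NEFM by 3.13, and the neural crest factor FOXD3 by 8.47, while the neuronal genes STMN2 and SNAP25 fell by 1.03 and 1.57. For fibroblast and mesenchyme markers 3 of 10 rose and 5 fell (camera adjusted p = 0.342), with THY1 at -2.63 and LUM at -2.03. Smooth muscle markers split into 5 higher and 6 lower of 11 (camera adjusted p = 0.515), with the actin regulator CALD1 at -1.96 and SYNPO2 at 1.59. Of 6 cardiac genes 5 rose (camera adjusted p = 0.128), among them the calcium release channel RYR2 by 5.37 and MYH6 by 1.25, and TNNI3, cardiac troponin I, had a log2 difference of -1.79. Of 5 endothelial genes 1 rose and 3 fell (camera adjusted p = 0.357), including the receptor TEK (-3.40) and EMCN (-1.65). Of 4 epithelial genes 2 rose and 1 fell (camera adjusted p = 0.296). CDH1, E-cadherin, rose by 6.47, from 0.441 ± 0.101 to 39.9 ± 0.740 CPM, and the epithelial transcription factor GRHL2 by 2.22. Only 1 of these 4 genes, CDH1, passed the stricter filter on low counts, so GRHL2 lay below it. EPCAM, KRT8, KRT18, KRT19 and KRT7 had at most 12 reads in any library and were not tested. Of 12 pluripotency genes only DNMT3B, a DNA methyltransferase, had enough reads to be tested (0.10, adjusted p = 0.167), and the list itself was not tested. DNMT3B was called lower under scaling by library totals (-0.19, adjusted p = 0.0163) and higher with upper-quartile factors (0.14, adjusted p = 0.0489) and with the stricter filter (0.14, adjusted p = 0.0425), so its direction depends on the scaling.

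In total 6673 of 17409 genes tested were higher in MyoT-Lam and 7068 lower, 3226 and 2368 of them by more than 2-fold, and 3668 were not called. Camera called 10 of 26 lists higher and 3 lower; the calls for excitation-contraction coupling (adjusted p = 0.0121), cell cycle (0.0121), interstitial matrix (0.025) and cholesterol synthesis (0.0461) held with an estimated correlation. For every list, the counts adjusted over the list alone were those over all genes. Scaling by library totals moved the median of all genes by -0.28 and gave 4865 higher and 9380 lower genes, 34.2% higher against 48.6%, so that all changes are relative to the scaling, and a test against a 1.5-fold change called 3866 and 3337. MyoB and MyoT-Lam differed in medium, plating density and substrate as well as in cell state. Of the genes named here MYH7, TMOD4, TNNT1, CDKN1C, ETV5, CHRNA1, CHRNE, PVALB, TPM3, SREBF2, CKMT2, UQCRC1, CPT1B, COX7A1, LDHB, LDHA, PKM, GAPDH, FN1, ELN, SPARC, FOXD3, STMN2, SNAP25, TNNI3 and TTN were chosen after their values were seen, and values of the closely related MYH and troponin genes and of FOXD3, which neighbours FOXD3-AS1, are uncertain where reads were split between them.

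Myotubes on Geltrex were compared with the myoblasts on the same substrate to ask how the cell states differ there. MYBPC1 rose 76.7-fold, from 14.5 ± 0.722 CPM in MyoB to 1108 ± 71.6 CPM in MyoT-Gtx, MYH3 from 956 ± 85.1 to 6862 ± 461 CPM and MYOG from 200.5 ± 6.55 to 715 ± 37.7 CPM. MKI67 dropped 12.2-fold to 61.4 ± 4.93 CPM, and the cell cycle gene RRM2, a ribonucleotide reductase subunit, fell by 3.69 on the log2 scale. POSTN dropped 19.4-fold to 28.4 ± 1.69 CPM.

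PAX7 had a log2 difference of -0.36 (adjusted p = 6.67e-06), MYF5 fell by 1.81 and MYOD1 rose by 0.54 (adjusted p = 1.01e-05). MYOG rose by 1.83 (SE 0.056, adjusted p = 7.49e-14), MYMK by 2.49 and DMD by 2.66. FATE1 and HS6ST3, with 0 reads in MyoB, were at least 231-fold and at least 200-fold higher, SLN had a ratio of 1330 (454 to 6440) and ADCY2 of 924 (165 to 36600). PRKAA2 rose to 73.7 ± 2.57 CPM, and PPP1R3A, a muscle glycogen phosphatase subunit, rose by 8.86 on the log2 scale. MYOCD had 2 reads in MyoT-Gtx and was 154-fold lower (42.4 to 1280). F2RL2 fell by 6.46, L1CAM by 6.19, CPA4 by 6.06 and ID3 by 5.37, and KITLG, the ligand of the KIT receptor, fell by 5.36.

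Of 41 sarcomere genes 38 rose and 3 fell (median 3.27, camera adjusted p = 1.33e-13; adjusted p = 0.105 with an estimated correlation). MYH7 fell by 2.10, TMOD4 by 1.78 and TNNT1 by 0.69. TMOD4 had few reads, with 1.14 to 1.47 CPM in MyoB and 0.208 to 0.502 CPM in MyoT-Gtx, the lowest at the detection floor. The differentiation and fusion list again had 21 of 22 genes higher (median 2.83, camera adjusted p = 1.19e-10; adjusted p = 0.0643 with an estimated correlation), with CDKN1C at -0.27. That call ended without MyoT-Gtx replicate 1 (-0.24, adjusted p = 0.0673), without MyoT-Gtx replicate 2 (-0.15, adjusted p = 0.11) and with a stricter filter on low counts (-0.22, adjusted p = 0.0587). All 22 excitation-contraction coupling genes rose (median 2.63, camera adjusted p = 1.19e-10), ATP2A1 by 4.22 and CACNA1S by 3.91. For the neuromuscular junction 13 of 16 genes rose, ETV5 fell by 0.66 and CHRNA1 and CHRNE differed by 0.03, or -0.25 under scaling by library totals (adjusted p = 4.65e-05), and -0.01 (median 1.08, camera adjusted p = 0.000404; adjusted p = 0.0825 with an estimated correlation). The dystrophin complex and membrane repair list had 13 of 19 genes higher and 6 lower (median 1.58, camera adjusted p = 0.011; adjusted p = 0.0825 with an estimated correlation). Fast fibre genes rose in 12 of 13 cases (median 4.15, camera adjusted p = 4.85e-06; adjusted p = 0.131 with an estimated correlation), with PVALB lower by a log2 difference of -4.75. Slow fibre genes included 8 higher and 3 lower of 11, MYH7, TNNT1 and TPM3 (-1.42) among the lower ones, and camera made no call (median 1.64, adjusted p = 0.0767). It called the list higher under scaling by library totals (median 1.37, adjusted p = 0.0162). The progenitor and myoblast list had 6 higher and 12 lower of 19 (median -0.36, camera adjusted p = 0.175), DLK1 being higher by 5.84.

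All 27 cell cycle genes fell (median -3.01, camera adjusted p = 6.08e-13), and 16 of 18 cholesterol and fatty acid synthesis genes fell (median -1.09, camera adjusted p = 4.01e-05), SCD by 1.89. SREBF2 was 0.15 higher, or called lower under scaling by library totals (-0.12, adjusted p = 0.0319). Oxidative metabolism genes were higher for 12 of 17 and lower for 2, CPT1B (-0.82) and UQCRC1 (-0.47), with a median of 0.52 (camera adjusted p = 0.00455; adjusted p = 0.101 with an estimated correlation), SLC25A4 rising by 1.81. CKMT2 (-0.16), COX7A1 (0.12) and LDHB (0.10, adjusted p = 0.0961) were not called. CKMT2 was called lower under scaling by library totals (-0.43, adjusted p = 0.00394). LDHB was called higher by DESeq2 (adjusted p = 0.0323), with RLE (0.0386) or upper-quartile factors (0.016), with a stricter filter on low counts (0.0143), without MyoB replicate 3 (0.13, adjusted p = 0.0337) and without MyoT-Gtx replicate 3 (0.15, adjusted p = 0.00819), and lower under scaling by library totals (-0.18, adjusted p = 0.00133). Glycolysis and glycogen genes rose in 13 of 16 cases (median 0.84, camera adjusted p = 0.000619; adjusted p = 0.227 with an estimated correlation), and LDHA and PKM fell by 1.52 and 0.51. GAPDH was at 0.05, or called lower under scaling by library totals (-0.22, adjusted p = 0.000143). Interstitial matrix genes fell in 20 of 22 cases (median -1.38, camera adjusted p = 1.5e-07), LOX by 3.04 and FN1 from 4312 ± 93.7 to 540.3 ± 17.4 CPM. ELN rose by 4.04, and SPARC differed by 0.06 (adjusted p = 0.282), by -0.22 under scaling by library totals (adjusted p = 0.000216), and was called higher without MyoT-Gtx replicate 3 (0.13, adjusted p = 0.00671). The FGF, ERK and cAMP response list had 15 of 23 genes higher and 7 lower (median 0.69, camera adjusted p = 0.0331; adjusted p = 0.339 with an estimated correlation and 0.0563 with a stricter filter on low counts), with EGR1 at 1.82 and ETV4 at -3.11.

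No call was made for integrin adhesion (13 higher, 11 lower of 25, camera adjusted p = 0.607), for basement membrane (7 and 8 of 21, median 0.00, mean -0.01, adjusted p = 0.654), for YAP and TEAD targets (7 and 13 of 21, adjusted p = 0.148) or for the Notch pathway (4 and 6 of 13, adjusted p = 0.291). ITGA6 rose by 1.55, LAMA2 by 3.50 and the Notch receptor NOTCH2 fell by 1.33. Stress genes had 4 higher and 8 lower of 16 (camera adjusted p = 0.255) and interferon response genes 8 higher and 4 lower of 13 (median 0.43, adjusted p = 0.452), with IFI44L at -1.72 and IFI44 at -1.80. Among markers of other cell types, camera gave adjusted p = 0.233 for neural and Schwann cells (6 higher, 3 lower of 12; called higher with a stricter filter on low counts that left 5 genes, median 2.99, adjusted p = 0.00396), 0.285 for fibroblasts (3 and 5 of 10) and 0.452 for smooth muscle (5 and 6 of 11). It gave 0.146 for cardiac muscle (5 and 1 of 6), 0.495 for endothelium (2 and 3 of 5) and 0.452 for epithelium (2 and 1 of 4). DCX rose by 2.94, CDH1 by 6.50 and RYR2 by 5.00, while PDGFRB, a receptor of mesenchymal cells, fell by 2.28 and TAGLN, a smooth muscle actin-binding protein, by 1.90. DNMT3B was 0.16 higher (adjusted p = 0.0384), but was not called without MyoB replicate 1 (0.16, adjusted p = 0.0788), MyoB replicate 3 (0.13, adjusted p = 0.121) or MyoT-Gtx replicate 2 (0.12, adjusted p = 0.144), without a filter on low counts (adjusted p = 0.165) or with the replicate number as a block (0.0575). It differed by -0.12 under scaling by library totals.

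Across the genes tested 6610 were higher in MyoT-Gtx and 6914 lower, 3219 and 2427 of them by more than 2-fold, and 3885 were not called. Camera called 9 lists higher and 3 lower, of which excitation-contraction coupling (adjusted p = 0.0122), cell cycle (0.0122), interstitial matrix (0.0213) and cholesterol synthesis (0.0496) held with an estimated correlation, and counts adjusted over the list alone were again those over all genes. Library totals moved the median of all genes by -0.28, with 4833 higher and 9205 lower genes, 34.4% higher against 48.9%, and the test against a 1.5-fold change called 3822 and 3316. Medium and plating density differed between MyoB and MyoT-Gtx along with cell state. The genes named outside the rule here were IFI44L and those so marked in the comparison on Laminin-521.

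Both myotube groups were compared with the same MyoB libraries, so their values share the chance part of those libraries. Of the genes higher than in MyoB 6330 were called in both groups, 94.9% of those in MyoT-Lam, where independent lists would share 2534, and 6615 lower genes were called in both, 93.6%, where 2807 would be shared. In 20 simulations of unchanged groups, all 9 libraries, the controls included, were drawn around the MyoB means. At most 1 gene per direction was called in both. Deviations particular to the real MyoB libraries were not simulated. The log2 differences of both groups correlated at 0.9913 across 15226 genes, which are not independent replicates, against 0.492 in the simulations, and their covariance was 1.415 against 0.0077 simulated, a difference of 1.407. With 3 control libraries no split kept a pair in each part, so part of the excess of the gene counts over independent lists may come from the shared controls. The difference in covariance leaves out their simulated part. ISG15, an interferon-induced ubiquitin-like protein, was lower than in MyoB on Laminin-521 (-0.32) and higher on Geltrex (0.28). Its calls ended without MyoB replicate 2 on Laminin-521 (-0.24, adjusted p = 0.0734), and on Geltrex without MyoB replicate 1, MyoB replicate 3, MyoT-Gtx replicate 1 or MyoT-Gtx replicate 3 (0.22 to 0.24, adjusted p = 0.0722 to 0.0982), while scaling by library totals gave -0.002 on Geltrex.

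MyoT-Lam was compared with MyoT-Gtx to ask what the substrate changes in myotubes kept in the same medium for the same time. Of 13 interferon response genes 6 were lower on Laminin-521 and of 22 interstitial matrix genes 5 were slightly higher, while none of the 8 fixed myogenic genes was called. IFI44L was 3.44-fold lower (1.48 ± 0.210 CPM in MyoT-Lam, 4.95 ± 0.0939 in MyoT-Gtx) and IFI6, another interferon-induced gene, was 1.90-fold lower (17.01 ± 1.195 against 32.7 ± 4.08 CPM). FNDC1, a fibronectin type III domain protein, was 2.09-fold higher (11.1 ± 0.0257 against 5.30 ± 0.0918 CPM), and FN1 1.28-fold higher (690.0 ± 22.6 against 540.3 ± 17.4 CPM).

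Of 13 interferon response genes tested 6 fell on Laminin-521, 9 adjusted over the list alone, and none rose (median -0.59, camera adjusted p = 1.87e-15; adjusted p = 0.00303 with an estimated correlation). IFI44L had a log2 difference of -1.78 (SE 0.135, adjusted p = 2.56e-05) and IFI6 of -0.92 (SE 0.087, adjusted p = 0.000155). The antiviral genes OAS2, MX1 and OAS3 differed by -2.27, -1.67 and -0.97, and ISG15 by -0.59. Expression of these antiviral genes was low in the myotubes. Over the MyoT-Gtx libraries OAS2 ranged from 0.67 to 1.2 CPM, MX1 from 2.1 to 2.8 and OAS3 from 2.4 to 3.8. Over the MyoT-Lam libraries the ranges were 0.091 to 0.249, 0.60 to 0.92 and 1.4 to 1.9 CPM. A stricter filter on low counts left 8 of the 13 list genes, and the list was still called lower. IRF9, a transcription factor of interferon signalling outside the list, differed by -0.49. Relative to MyoB, IFI44L and OAS3 were lower in both myotube groups, while OAS2, MX1 and IFI6 were higher in MyoT-Gtx. ISG15 was too, though not in every fit, as given above. Without MyoT-Gtx replicate 3, the library that stood apart, the list median was -0.52. Leaving out a library ended the call of ISG15 for each MyoT-Lam replicate and for MyoT-Gtx replicate 1 (adjusted p = 0.0544 to 0.139), of OAS2 for MyoT-Lam replicates 1 and 2 and MyoT-Gtx replicates 1 and 3 (0.0583 to 0.129), of OAS3 for every library but MyoT-Gtx replicate 2 (0.0721 to 0.29), and of IRF9 for MyoT-Lam replicates 1 and 3 and MyoT-Gtx replicate 1 (0.0629 to 0.0939). IFI44L (gene 10964) lies on chromosome 1 from 78620448 to 78646145, IFI6 (gene 2537) on chromosome 1 from 27666064 to 27672192, MX1 (gene 4599) on chromosome 21 from 41420558 to 41459214, and OAS2 (gene 4939) on chromosome 12 from 112978519 to 113011723.

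Of 22 interstitial matrix genes 5 rose, 14 adjusted over the list alone, and none fell (median 0.14, camera adjusted p = 1.21e-12; adjusted p = 0.00689 with an estimated correlation). FN1 rose by 0.35 (SE 0.043, adjusted p = 0.002), the proteoglycan gene BGN by 0.37, the thrombospondin gene THBS2 by 0.47, and COL1A1 and LOX by 0.21 each. These 5 genes were lower in both myotube groups than in MyoB, where FN1 stood at 4312 ± 93.7 CPM. The list median was 0.13 without MyoT-Gtx replicate 3. LOX lost its call whichever of the 9 libraries was left out (adjusted p = 0.0562 to 0.175), COL1A1 without MyoB replicates 1 and 2, each MyoT-Lam replicate and MyoT-Gtx replicates 1 and 2 (0.0671 to 0.154), and THBS2 without MyoT-Lam replicates 1 and 3 and MyoT-Gtx replicate 2 (0.0625 to 0.0861). FN1 (gene 2335) spans 215360865 to 215436068 of chromosome 2 and FNDC1 (gene 84624) spans 159169400 to 159272108 of chromosome 6.

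**Figure D3:**
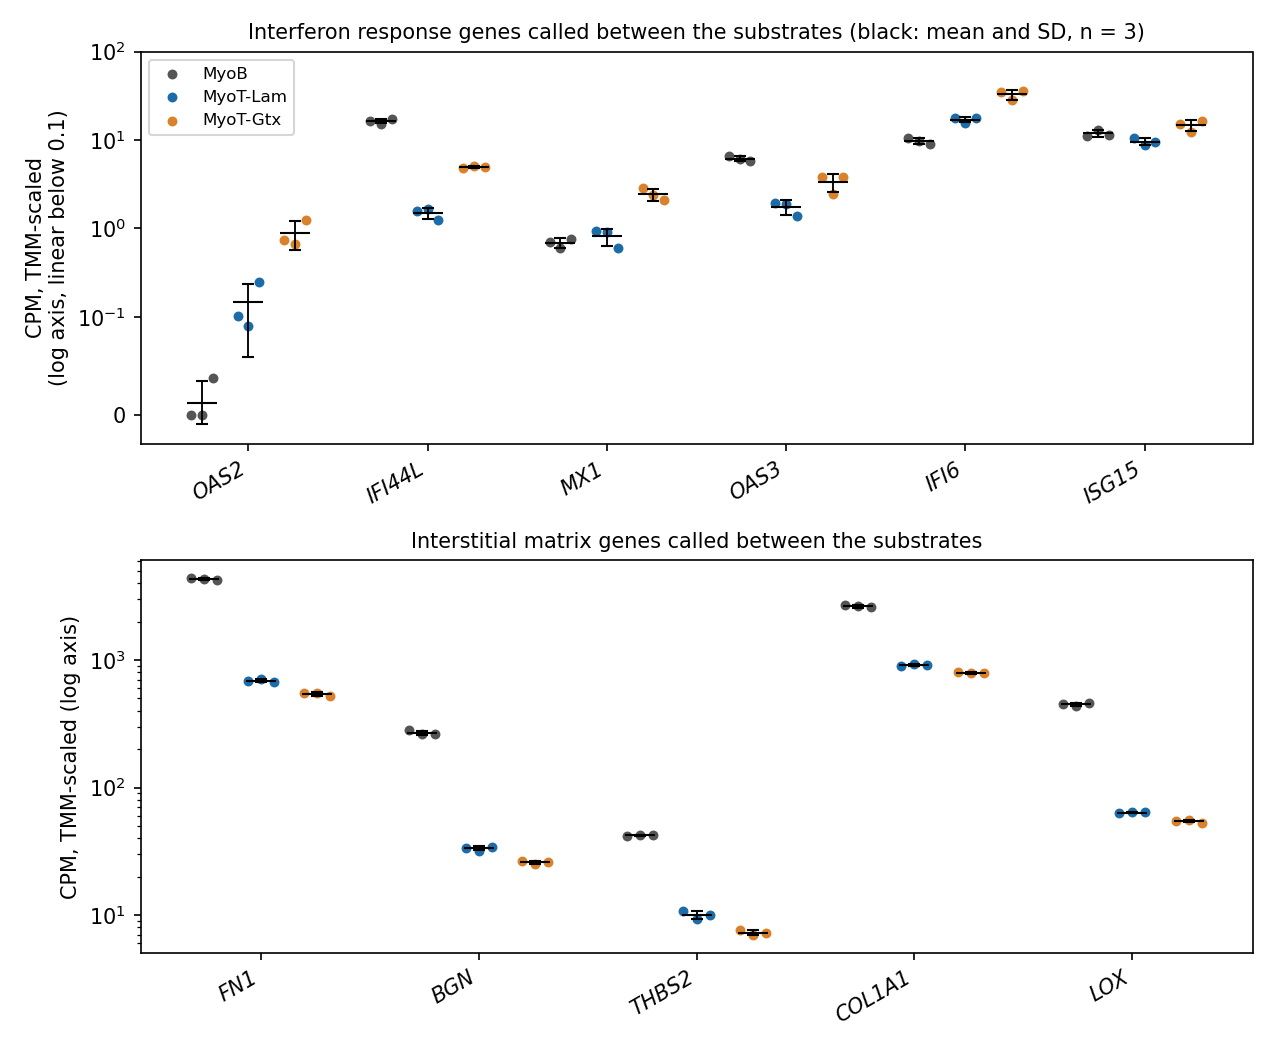
CPM per library (points) with the group mean and SD (black, n = 3) of the interferon response genes (upper panel, log axis that is linear below 0.1) and interstitial matrix genes (lower panel, log axis) called between MyoT-Lam and MyoT-Gtx. IFI6 stands at 17.01 CPM in MyoT-Lam and 32.7 in MyoT-Gtx, and FN1 at 690.0 and 540.3.

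Further adhesion and matrix-related genes were higher on Laminin-521. In the integrin adhesion list 2 of 25 genes rose, 3 adjusted over the list alone (camera adjusted p = 0.00335; adjusted p = 0.0701 with an estimated correlation), namely the collagen-binding integrins ITGA11 (0.40, adjusted p = 0.00125) and ITGA1 (0.38). Among basement membrane genes NID2, a nidogen, rose by 0.29, 1 of 21 genes and 2 adjusted over the list alone (camera adjusted p = 0.00382; adjusted p = 0.0701 with an estimated correlation). YAP and TEAD targets had 3 of 21 genes higher, 4 adjusted over the list alone (camera adjusted p = 0.00627; adjusted p = 0.198 with an estimated correlation). They were CCN2 (0.40, adjusted p = 0.000985), CRIM1 (0.28) and CCN1 (0.26), the CCN genes encoding matricellular proteins. Fibroblast markers had 2 of 10 genes higher, MFAP5 (0.67) and OGN (0.33), and 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.017; adjusted p = 0.226 with an estimated correlation). TAGLN (0.29) was the 1 called of 11 smooth muscle genes, 5 adjusted over the list alone (camera adjusted p = 0.00335; adjusted p = 0.0836 with an estimated correlation). Leaving out a library ended the calls of ITGA1 (MyoT-Lam replicate 1, adjusted p = 0.074), NID2 (MyoT-Lam replicates 2 and 3, 0.0552 and 0.0658), CRIM1 (each MyoT-Lam replicate and MyoT-Gtx replicate 1, 0.0547 to 0.092) and CCN1 (MyoB replicate 1, each MyoT-Lam replicate and MyoT-Gtx replicates 1 and 2, 0.0566 to 0.145). The same held for MFAP5 (each MyoT-Lam replicate and MyoT-Gtx replicates 1 and 2, 0.0584 to 0.104), OGN (MyoB replicate 1, each MyoT-Lam replicate and MyoT-Gtx replicates 1 and 3, 0.0604 to 0.167) and TAGLN (MyoB replicate 1, MyoT-Lam replicates 1 and 3 and MyoT-Gtx replicate 2, 0.055 to 0.143), and for the list calls of YAP and TEAD targets (MyoT-Lam replicate 3, 0.116) and fibroblast markers (MyoT-Lam replicate 3, 0.112, and MyoT-Gtx replicate 3, 0.104).

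Few fibre type genes were called. MYH7 rose by 0.89 (4.87 ± 0.663 against 2.65 ± 0.259 CPM, adjusted p = 0.00652) and TNNT1 by 0.62 (18.4 ± 1.71 against 11.9 ± 2.19 CPM), 2 of 11 slow fibre genes both over all genes and adjusted over the list alone (camera adjusted p = 0.0123; adjusted p = 0.262 with an estimated correlation). ACTN3, the fast fibre alpha-actinin, fell by 0.50, 1 of 13 fast fibre genes, and adjusted over the list alone 4 were lower and 1 higher (camera adjusted p = 0.0041; adjusted p = 0.284 with an estimated correlation). TNNT1 lost its call without MyoT-Lam replicates 1 and 3 and MyoT-Gtx replicate 2 (adjusted p = 0.0855 to 0.106), and ACTN3 without MyoB replicate 1 and without each myotube library (0.055 to 0.141). Among cardiac genes RYR2 rose by 0.37 (98.2 ± 0.964 against 75.8 ± 6.04 CPM), 1 of 6 genes both ways of adjusting (camera adjusted p = 0.243). EMCN was the 1 of 5 endothelial genes called (-0.33), 2 lower adjusted over the list alone (camera adjusted p = 0.0102; adjusted p = 0.107 with an estimated correlation), and lost its call when any library except MyoB replicate 2 was left out (0.0671 to 0.197). The list calls ended for slow fibre genes without MyoT-Lam replicate 3 and MyoT-Gtx replicates 2 and 3 (0.0588 to 0.0784), for fast fibre genes without MyoT-Gtx replicate 1 (0.141) and for endothelial genes without MyoT-Lam replicate 3 (0.0665) and MyoT-Gtx replicate 2 (0.0572). The other genes named by the rule were LRATD2 (0.67), the kinesin gene KIF26B (0.61) and the vesicle trafficking gene RAB3B (0.60), which were higher, and TMEM52 (-0.53) and DDIT4L (-0.47), which were lower. TMEM52 was not called without MyoT-Lam replicates 1 and 2 or any MyoT-Gtx replicate (0.0639 to 0.175) and DDIT4L without each MyoT-Lam replicate and MyoT-Gtx replicates 1 and 2 (0.0564 to 0.1).

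The fixed myogenic genes had log2 differences between -0.05 (MYOD1, SE 0.072, adjusted p = 0.916) and 0.12 (DMD, SE 0.044, adjusted p = 0.412), with MYOG at -0.02 (SE 0.054) and MYH3 at 0.01 (SE 0.065). No single gene was called, over all genes, in the lists for differentiation and fusion (camera adjusted p = 0.0636), excitation-contraction coupling (0.666), the neuromuscular junction (0.506, 1 gene higher adjusted over the list alone), the dystrophin complex (0.906, median -0.01, mean 0.01, direction down), the Notch pathway (0.647, 2 higher and 1 lower adjusted over the list alone, median 0.04, mean -0.03, direction up), cholesterol synthesis (0.0636), stress (0.559, 1 higher adjusted over the list alone), neural and Schwann cells (0.588, median -0.04, mean 0.01, direction down) or epithelium (0.381). The sarcomere list held MYH7 and TNNT1 as its only called genes, with 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.559). Camera called the cell cycle list higher with no gene called (adjusted p = 0.0149; adjusted p = 0.207 with an estimated correlation) and the FGF, ERK and cAMP list higher with 4 genes higher and 1 lower adjusted over the list alone (adjusted p = 0.0498; adjusted p = 0.347 with an estimated correlation). It called progenitor genes (adjusted p = 0.0401; adjusted p = 0.46 with an estimated correlation), oxidative metabolism (0.0166; adjusted p = 0.198 with an estimated correlation) and glycolysis (0.000945; adjusted p = 0.221 with an estimated correlation) lower, each with 2 genes lower adjusted over the list alone. Leaving out a library ended the list calls of progenitor genes (any library except MyoT-Lam replicate 1 and MyoT-Gtx replicate 2, 0.0524 to 0.289), of the FGF, ERK and cAMP list (MyoB replicate 2, MyoT-Lam replicates 1 and 3 and MyoT-Gtx replicates 1 and 2, 0.0743 to 0.141), of cell cycle genes (MyoT-Lam replicate 3 and MyoT-Gtx replicates 2 and 3, 0.0535 to 0.112) and of oxidative metabolism (MyoT-Lam replicate 2, 0.0588, and MyoT-Gtx replicate 1, 0.0734). Differentiation and fusion genes were called lower without MyoT-Lam replicate 1 (0.0403) and MyoT-Gtx replicate 2 (0.0371), and cholesterol synthesis genes lower without MyoT-Lam replicate 1 (0.0329). MYOZ1, a fast fibre Z-disc gene, differed by -0.24 (adjusted p = 0.0574) and was called without MyoT-Gtx replicate 3 (-0.28, adjusted p = 0.0215). It was also called lower by DESeq2 (adjusted p = 0.0118), with upper-quartile factors (0.0415) and with library totals alone (0.0335). The same held without a filter on low counts (0.0161), with the stricter filter (0.0487) and with the GC content and transcript length offsets (0.0199), but not under the other alternatives.

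Between the substrates 56 genes were higher in MyoT-Lam and 22 lower, 2 and 3 of them by more than 2-fold, 17331 were not called, and 1543 had an unadjusted p under 0.05. Of the 56 higher genes 21 were called lower and 29 higher than in MyoB in both myotube groups, and of the 22 lower genes 6 were called lower than in MyoB in both. Simulated data had the same depths and the mean expression of MyoB. Among 16355 genes the test recovered 31.3% of those changed 1.2-fold, 82.1% of those changed 1.5-fold and 90.9% of those changed 2-fold. Of its calls 8.11% were false. Recovery of genes with few reads was not simulated. Camera called 9 lists higher and 6 lower, of which interferon response and interstitial matrix held with an estimated correlation, though interstitial matrix did not once the GC content and transcript length offsets were added too (adjusted p = 0.115), and there were 4 higher lists without MyoT-Lam replicate 3 and 3 lower lists without MyoT-Gtx replicate 1. OAS2, MX1, OAS3, THBS2, COL1A1, LOX and CCN1 were chosen after their values were seen.

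Leaving out a library gave 37 higher and 13 lower genes without MyoB replicate 1, 17 and 3 without MyoT-Lam replicate 1, 26 and 7 without MyoT-Lam replicate 2, 21 and 8 without MyoT-Lam replicate 3, 31 and 7 without MyoT-Gtx replicate 1, and 37 and 20 without MyoT-Gtx replicate 2. DESeq2, which gave no adjusted p for 4726 of 17409 genes, called 96 and 35. The fit without a filter on low counts called 90 and 39 genes and the fit of only the 6 myotube libraries 28 and 11. Offsets for GC content and transcript length, added after the data were examined, gave 111 and 48, and the test against a 1.5-fold change 1 and 1. The replicate block ended the calls of OAS3, COL1A1, LOX, ACTN3, OGN, EMCN and CCN1 (adjusted p = 0.0669 to 0.0944). The fit of only the 6 myotube libraries ended these calls and those of THBS2, ITGA1, CRIM1, TAGLN and TMEM52 (0.0679 to 0.151).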

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

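The tests of remaining myoblasts and of MyoT-Gtx replicate 3 were chosen only after the result was seen, and the offsets for GC content and transcript length were added after the data were examined. Each gene given here stood out because its change from MyoB on Laminin-521 differed from its change from MyoB on Geltrex, tested as the difference between both myotube groups; the values are log2 differences, MyoT-Lam minus MyoT-Gtx. Groups of 3 libraries were too small to test single libraries for standing apart.

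Interferon response genes were lower on Laminin-521: OAS2 (-2.27), IFI44L (-1.78), MX1 (-1.67), OAS3 (-0.97), IFI6 (-0.92) and ISG15 (-0.59). OAS2, MX1 and OAS3 had low CPM in both myotube groups, as given above. After offsets that removed each library's trend with GC content and transcript length 7 list genes were lower, the 6 of the test without offsets among them, with a list median of -0.515 against -0.59, which argues against such a trend as the whole cause. The tests of remaining myoblasts take such cells to match the MyoB libraries. Cells left in the myotube cultures had another medium and plating density, so remaining cells that differ from MyoB stay open. More myoblasts like those of MyoB on Geltrex could not give the difference for OAS2, MX1 and IFI6, 3 of the 4 genes called higher in MyoT-Gtx than in MyoB. The other, ISG15 (0.275), lost that call without MyoB replicate 1 or 3 or MyoT-Gtx replicate 1 or 3 (adjusted p = 0.0722 to 0.0982) and was at -0.002 under scaling by library totals; even at that value, where MyoT-Gtx matches MyoB, nearly all cells on Geltrex would have to be myoblasts. IFI44L and OAS3 would need a difference in myoblast share of at least -30.6%, against 0.543% from 114 other genes that are far lower in myotubes. The 95% interval of 0.325 to 0.651 came from resampling these 114 genes, whose quartiles were 0.0279 and 1.14. It holds no spread between libraries. Without MyoT-Gtx replicate 3 the list median was -0.521. A response of the myotubes to the substrate, or to something the substrates carry, may underlie this and stays open as a hypothesis, since no test here separates the substrate from other differences between the cultures.

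Interstitial matrix genes were higher on Laminin-521: THBS2 (0.47), BGN (0.37), FN1 (0.35), LOX (0.21) and COL1A1 (0.21). With the same offsets 7 list genes were higher, 4 of the original 5 among them, and the list median was 0.106 against 0.136 (camera adjusted p = 1.16e-10), which argues against a GC or length trend as the whole cause. With the offsets and the correlation estimated from the data together the list was not called (adjusted p = 0.115). As the median was smaller with the offsets, part of the difference may come from such a trend. More myoblasts like those of MyoB left on Laminin-521 would need a share difference of 2.22% to 7.81% for these genes, against the estimated 0.543%. That estimate holds no spread between libraries, and remaining cells that differ from MyoB stay open. Without MyoT-Gtx replicate 3 the list median was 0.131. Lists for other cells that make matrix moved the same way in their medians, though few of their genes were called. Fibroblast and mesenchyme genes had a median of 0.164, with 2 of 10 called higher (camera adjusted p = 0.017). The adjusted p was 0.226 with an estimated correlation, 0.112 without MyoT-Lam replicate 3 and 0.104 without MyoT-Gtx replicate 3. Smooth muscle genes had a median of 0.151, with 1 of 11 called higher (camera adjusted p = 0.00335, or 0.0836 with an estimated correlation). More of such cells on Laminin-521 was not tested and stays open beside a response to the substrate, which may underlie these small differences as a hypothesis found and tested on the same libraries.

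Other genes were higher on Laminin-521. They were FNDC1 (1.06), MYH7 (0.89), MFAP5 (0.67), LRATD2 (0.67), TNNT1 (0.62), KIF26B (0.61), RAB3B (0.60), FRAS1 (0.44), ITGA11 (0.40), CCN2 (0.40), ITGA1 (0.38), RYR2 (0.37), OGN (0.33), TAGLN (0.29), NID2 (0.29), CRIM1 (0.28) and CCN1 (0.26). Lower on Laminin-521 were TMEM52 (-0.53), ACTN3 (-0.50), IRF9 (-0.49), DDIT4L (-0.47) and EMCN (-0.33). FRAS1, which encodes an extracellular matrix protein, was chosen after its value was seen.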

How the results depend on the processing

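The offsets for GC content and transcript length were chosen after the data were examined; all other alternatives were set before. For MyoT-Lam against MyoB, 94 of the 107 named genes called kept their call and direction under every alternative that tested them. For MyoT-Gtx against MyoB these were 97 of 110, but between the substrates only 2 of 33, FNDC1 and IFI44L. The test against a 1.5-fold change, which asks for larger changes, by itself ended 31 of these 33 calls. FN1, BGN, IFI6, MX1, MYH7, FRAS1, CCN2, ITGA11, RYR2, LRATD2, KIF26B and RAB3B lost their call only in that test. The remaining genes lost it under further alternatives too. Some named genes were not tested under every alternative. The stricter filter on low counts and the fit of only the 6 samples compared left some out. Between the substrates DESeq2 gave some of them no adjusted p. Under every alternative run camera or fry called the gene list interferon response, MyoT-Lam vs MyoT-Gtx, lower (median -0.709 to -0.484, adjusted p from 9.01e-18 to 0.00303) and the gene list interstitial matrix, MyoT-Lam vs MyoT-Gtx, higher (median 0.106 to 0.166, adjusted p from 1.16e-12 to 0.00689). With the GC content and transcript length offsets and the estimated correlation combined, the interstitial matrix list lost its call (adjusted p = 0.115) and the interferon response list kept it (0.00278). Against a 1.5-fold change 3866 genes were higher and 3337 lower in MyoT-Lam than in MyoB, 3822 and 3316 in MyoT-Gtx, 3650 were genes higher than in MyoB in both myotube groups and 3097 lower in both, and 1 and 1 between the substrates, as this test asks for larger changes. Between the substrates DESeq2 called 96 higher and 35 lower genes, no filter on low counts gave 90 and 39 and only the 6 samples compared gave 28 and 11. The GC content and transcript length offsets gave 111 and 48, of which 74 were among the 78. Fewer libraries estimate the spread in the fit of 6 samples. DESeq2 gave no adjusted p for 4726 of 17409 genes, so it adjusted over fewer genes, with an effect on its calls that was not tested. For the others the cause was not tested either. Leaving out a library gave 17 to 53 higher and 3 to 22 lower genes there, the fewest without MyoT-Lam replicate 1, and 4 to 9 higher (4 without MyoT-Lam replicate 3) and 3 to 8 lower lists (3 without MyoT-Gtx replicate 1). With an estimated correlation 1 list stayed higher in each comparison, against 10, 9 and 9, and 1 lower between the substrates, against 6. Fry, which does not compare a list with other genes, called 12 lists lower in MyoT-Lam than in MyoB, 14 higher and 11 lower in MyoT-Gtx than in MyoB and 3 lower between the substrates. With the stricter filter on low counts the gene list neural and Schwann cell was called higher than in MyoB on both substrates (median 3.086 and 2.988), on 5 of its 12 genes, while slow fibre lost its call in MyoT-Lam (adjusted p = 0.104) and FGF, ERK and cAMP response in MyoT-Gtx (0.0563). Scaling by library totals called slow fibre higher in MyoT-Gtx (0.0162) and, between the substrates, differentiation and cholesterol synthesis lower (0.0467 each), and ended the calls of progenitor (0.0505) and FGF, ERK and cAMP response genes (0.0525), as did the replicate block (0.0649 and 0.0541). Scaling by library totals reversed DNMT3B (-0.19), SPARC (-0.14), SREBF2 (-0.094), LDHB (-0.24) and GAPDH (-0.26) in MyoT-Lam against MyoB and DNMT3B (-0.12), SPARC (-0.22), SREBF2 (-0.12), ISG15 (-0.002), CHRNA1 (-0.25), LDHB (-0.18) and GAPDH (-0.22) in MyoT-Gtx against MyoB, as it lowers the median of all genes by about as much, and it called 177 and 164 genes in the opposite direction. With the replicate number as a replicate block 6641 and 6988, 6576 and 6861, and 42 and 17 genes were called. In their deviations from the group means, same-numbered libraries correlated at -0.108 to 0.096 in 9 pairs. Of 9 libraries 1 matched its own number best. These correlations over all genes showed no pairing by number, but with 3 libraries per group they cannot exclude it. The share of short and structural RNA was lowest in replicate 2 of each group (MyoB 4.42%, MyoT-Lam 6.06%, MyoT-Gtx 6.38%). Replicates 1 and 3 had no common order. At these depths 1.2-fold changes were mostly not recovered in simulated data, 41.8%, 25.4% and 31.3% in the 3 comparisons.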

Other observations

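The tests of neurons and of scaling were chosen only after the result was seen. Genes known from neurons and neural crest were among those higher in both myotube groups than in MyoB, by log2 differences of 3.04 and 2.94 for DCX, 3.13 and 3.17 for NEFM, 2.21 and 2.30 for the neurofilament gene NEFL and 8.47 and 8.51 for FOXD3, on Laminin-521 and Geltrex. Neurons in the myotube cultures would bring their abundant transcripts along. STMN2 (1.48 CPM in MyoB, 0.697 in MyoT-Lam and 0.632 in MyoT-Gtx) and SNAP25 (4.40, 1.41 and 1.85) were lower in both, the highest log2 difference being -1.03. Both belong to the same list, of which 6 of 12 tested genes rose and 3 fell in each myotube group. As these 2 genes were picked after the values were seen, they cannot decide whether neurons were the source. Over the other scalings the lowest log2 difference of the 4 genes was 1.92, so scaling does not account for them. Transcription of DCX, NEFM, NEFL and FOXD3 in the myotubes themselves may be the source, a hypothesis that bulk RNA cannot test further. Neurons and other neural cell types, Schwann cells among them, stay open.

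Splits of the samples were used to ask whether other groupings give as much. For each comparison the 6 libraries can be split 10 ways into 3 and 3, too few for a share under 0.05. The real grouping was the 1 split of 10 with as many genes in every comparison, with 13741 genes for MyoT-Lam against MyoB (highest other split 0), 13524 for MyoT-Gtx against MyoB (highest other 0) and 78 between the substrates (highest other 3). It was also the 1 split with as many lists, 13 (highest other 11), 12 (highest other 10) and 15 (highest other 4). For the overlap of both myotube groups, 100 splits of the 9 libraries into 3 groups of 3 were drawn. The 6330 genes higher in both were reached by 1 of them, the real one (next 6316). As many as the 6615 lower in both were reached by 2 (highest other 6619). A split that mixes MyoB with myotube libraries puts the large difference between cell states into the spread within groups, so calls could hardly follow. The splits thus show only that the MyoB libraries differ from the myotube libraries in these samples, whose replicates may be technical. The 3 drawn splits that kept the MyoB libraries together, the real one included, gave 6307 to 6330 higher and 6604 to 6619 lower genes. The other 97 gave 0. The counts thus do not depend on how the myotube libraries were divided and say nothing on the overlap between the substrates.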
